A study of Homo sapiens with 2 samples.

How the data were processed

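Gene expression was measured on 2 Affymetrix 3' expression arrays, both hybridised with RNA from MCF-7 cells, an estrogen receptor-positive human breast cancer line. Per the labels' protocols, cells were stained with ALDEFLUOR, a fluorescent substrate that is trapped in cells with aldehyde dehydrogenase (ALDH) activity. ALDH-positive and ALDH-negative cells were then sorted by flow cytometry, total RNA was extracted, and biotin-labelled cRNA was made from 250 ng of it with a 3' in vitro transcription kit. The labels give 1 array per sorted population and do not say whether either RNA pooled several sorts.

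The deposited values are linear signal intensities per probe set, computed by the authors with MAS5 per the submitters' processing notes; the version and the scaling target are not given in the sources used here. The table held 54613 probe sets, no negative values, no Affymetrix control probe sets and no detection calls. Trimmed means over the probe sets between the lowest 2% and the highest 2% were 496 on both arrays. That the arrays had been scaled to one target was read from this equality, so the signals were compared without another scaling in the main setting.

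Gene names came from the platform annotation held by GEO, updated by gene identifier through the RefSeq gene table for human. Of the probe sets, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none in that table. Of the 41091, 41037 matched a RefSeq gene and 54 kept the annotation's name; 0 symbols changed. Probe sets with several names or none stayed out of the gene analysis. No genome build was named for these values, so no coordinates are given. The RefSeq table was used only for names, for the order of neighbouring genes and for the gene density of chromosomes.

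A probe set was kept when the mean of its 2 signals reached the 60th percentile over all probe sets, a signal of 115.5, which left 18997 probe sets with 1 gene and 10671 genes of the 19775 annotated. Signals under the 40th percentile of their own array (40.5 on the ALDH-positive and 37.7 on the ALDH-negative array) were raised to it before log2 was taken. A fold with one side at this floor is a lower bound and is written as at least that many fold; medians and SDs that include such values rest on the floor. A gene was represented by its brightest kept probe set, and its difference is log2 ALDH-positive minus log2 ALDH-negative.

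With 1 array per group there was no replicate error, so no test, p-value or standard error was computed, and genes were counted by a fixed size of 2-fold. The number of arrays limits the precision of every value. The spread between kept probe sets of one gene is given as the SD over those probe sets; it holds probe behaviour and no biological variation. For 35 gene lists, the median difference of the kept members was placed as a percentile among 10000 random lists of the same size, drawn to match the list over 10 bins of mean signal. Lists with fewer than 5 kept genes were not placed. A list was counted as outside when its percentile lay below 2.5 or above 97.5, which describes these 2 arrays and not the populations.

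Genes were named by a rule. It took every measured gene of the ALDH family. Among genes with several kept probe sets that all differed the same way by at least 0.58 on log2, it took the 8 highest and 8 lowest median differences. Among genes with 1 kept probe set and a mean signal at or above the 75th percentile, it took the 4 highest and 4 lowest differences. It also took the members with the largest differences of each list, up to 4 for a list outside the percentile limits and up to 2 for any other, and ESR1, CD44, CD24, KRT8, KRT18 and MKI67. The list members MYC, EZH2, KLF4, ISG15, B2M, VEGFA, HES1, HEY1, AXIN2, FZD2, RNF43, SMAD7, ABCA12, ABCG2 and the 5 kept markers of other cells are outside this rule and were chosen after their values were seen. The rule, the lists, the filter, the floor and the other settings listed next were fixed before the data were examined.

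The other settings were median centring, quantile normalization, a loess correction of the difference on mean signal, no filter, filters at the 50th and 75th percentiles, no floor, a floor at the 20th percentile, the mean over all kept probe sets of a gene, and leaving out probe sets that the array design marks as shared between transcripts (the suffixes _x_at and _s_at). A further setting in which the median difference of each gene's 30 nearest kept genes was subtracted was chosen after seeing the data.

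The steps were tested on simulated arrays of 10670 genes with the filter and floor of this comparison. Of 100 genes given a log2 difference of 1.5, 93 passed 2-fold, and of 100 given a log2 difference of 3, 100 did. Of 10470 unchanged genes, 22 passed (0.21%). Of 100 unchanged lists, 3 lay outside the percentile limits, and 20 of 20 lists raised by 1 on log2 did. The noise was drawn independently for each probe set, with the median SD between probe sets of one gene in its bin of signal. Over all genes with several kept probe sets that median was 0.26, under the pooled SD of 0.41, so larger noise was left out. The noise held no variation between sorts, labellings or arrays, and none shared between genes. These shares are therefore not error rates of the real comparison. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.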

Results

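The data are 1 array of ALDH-positive and 1 array of ALDH-negative MCF-7 cells, sorted from the same line by ALDEFLUOR fluorescence. MAS5 signals ran from 0.1 to 77263 with a median of 65.4 on the ALDH-positive array, and from 0.2 to 74338 with a median of 60.4 on the ALDH-negative array. Across the 10671 kept genes the log2 signals of the arrays correlated with Pearson's r = 0.892 and Spearman's rho = 0.905; genes are not independent replicates. There are no replicate arrays, so every difference below is a difference between these 2 arrays without a replicate check.

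The comparison asks which transcripts distinguish MCF-7 cells with ALDEFLUOR activity, a property used to enrich for stem-like breast cancer cells, from those without it. ALDH1A3, which oxidises retinaldehyde to retinoic acid, had a signal of 1929 in ALDH-positive cells and 33.5 in ALDH-negative cells, at least 51.2-fold higher. The stem cell transcription factor SOX2 was 32.5-fold higher, the helix-loop-helix inhibitor ID1 13.7-fold higher and the caveolar protein CAV1 28.6-fold higher in ALDH-positive cells. The protease inhibitor CSTA was 269-fold lower, the imprinted gene PEG10 81.4-fold lower and the apoptosis inhibitor BCL2 20.1-fold lower. Lists of pluripotency and self-renewal factors and of basal markers stood higher in ALDH-positive cells than random lists of like signal, and a hypoxia list stood lower.

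In all, 983 genes (9.21%) were at least 2-fold higher and 660 (6.19%) at least 2-fold lower in ALDH-positive cells. At 8-fold or more there were 123 genes higher and 73 lower, and at 16-fold or more 52 higher and 34 lower. The median difference over all kept genes was 0.05 on log2. The count depended on the filter on dim probe sets: without it 1551 genes were at least 2-fold higher, and with the filter at the 75th percentile 468 were higher and 427 lower. The share of genes at 2-fold or more was 29.96% in the dimmest of 10 equal bins of genes and 7.03% in the brightest.

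Probe sets of one gene gave a measure of the spread between probe sets, which leaves out any error that a whole array shares. Over the 5043 genes with at least 2 kept probe sets, the pooled SD of the difference between probe sets was 0.41 on log2. Of 385 genes that were 2-fold higher by their brightest probe set, 368 (95.6%) were higher by their next brightest as well and 234 (60.8%) were 2-fold higher by it, against 53.7% and 8.80% of all genes with several probe sets. Of 253 genes that were 2-fold lower, 242 (95.7%) were lower by the next brightest and 162 (64.0%) were 2-fold lower, against 46.3% and 5.95%.

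**Figure D1:**
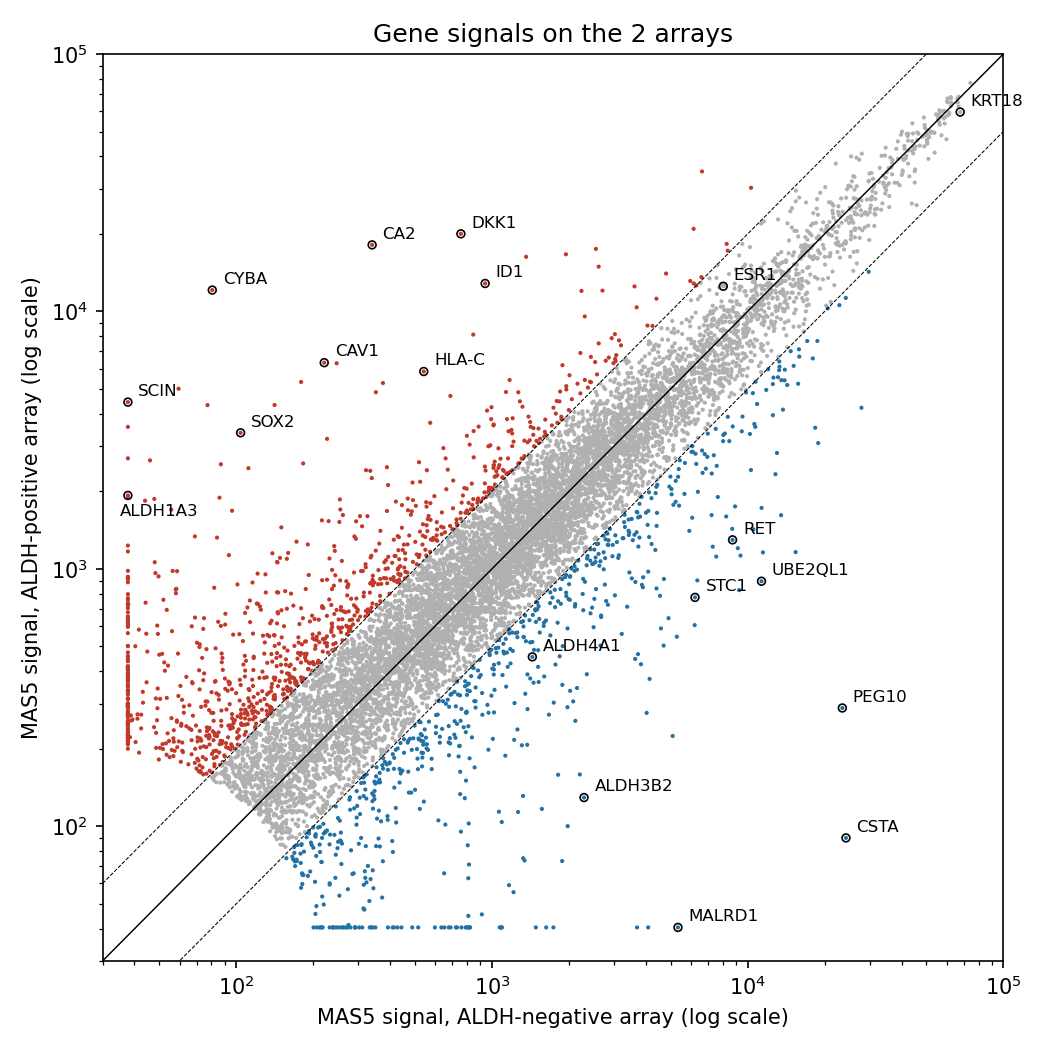
Signals of the 10671 kept genes on the ALDH-negative array (x axis) and the ALDH-positive array (y axis), both as MAS5 signal on a log scale. Each point is a gene, red points are the 983 genes at least 2-fold higher in ALDH-positive cells, blue points the 660 at least 2-fold lower, dashed lines mark 2-fold, and the points lined up at the left and at the bottom stand at the floor of 37.7 or 40.5.

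Of the 19 ALDH family genes measured, 12 were kept, and their differences went both ways. ALDH1A3 was higher by both of its probe sets, with differences of 2.48 and at least 5.68. ALDH3B2 was 17.7-fold lower in ALDH-positive cells (129 against 2292), with probe sets at -4.15 and, with the ALDH-positive side at the floor, at -2.73 or lower, and the mitochondrial ALDH4A1 was 3.16-fold lower (455 against 1439; probe sets at -1.66 and -1.60). ALDH3B1, ALDH16A1 and ALDH5A1 had differences of 0.94, 0.86 and 0.68, and the other kept probe set of ALDH3B1 differed by 2.20. ALDH6A1 at 0.34, ALDH7A1 at 0.28, ALDH3A2 at 0.25, ALDH1B1 at -0.07, ALDH18A1 at -0.18 and ALDH9A1 at -0.55 were under 2-fold, and the first 3 of these took the opposite sign when all of their kept probe sets were averaged. ALDH1B1's other kept probe set differed by -1.92, at 62.9 against 237. ALDH1A1, the isoform most often tied to ALDEFLUOR activity, was below the filter with signals of 5.0 and 1.9, as were ALDH1A2, ALDH1L1, ALDH1L2, ALDH2, ALDH3A1 and ALDH8A1. ALDH2 read 40.9 in ALDH-positive and 80.3 in ALDH-negative cells, and ALDH3A1 read 166 and 3.0. The family's median difference of 0.27 lay at percentile 86.1 of random lists, and at 29.4 when the kept probe sets of each gene were averaged.

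Among genes measured by several probe sets that moved the same way, the highest in ALDH-positive cells were TFPI2, SCIN, ZNF22, CDH26, SHH, CAV1, CALCR and HEY2. TFPI2, a Kunitz-type protease inhibitor, was 84.2-fold higher, and by at least 5.28 on log2 by its other probe set. SCIN, an actin-severing protein, was at least 118-fold higher, with a median over its 3 kept probe sets of at least 5.51. CDH26, a cadherin, was 29.7-fold higher, and the zinc finger gene ZNF22 at least 50.6-fold higher. The secreted ligand SHH was 56.1-fold higher by its brightest probe set and by at least 3.80 on log2 by its other one. The calcitonin receptor CALCR was at least 94.5-fold higher and the Notch-induced repressor HEY2 19.4-fold higher. CALCR's probe sets were far apart, at 2.40 and at least 6.56. Among genes with 1 bright probe set the highest were CYBA, a subunit of the NADPH oxidase (12107 against 80.6, 150-fold), AKR1C3, a steroid and prostaglandin reductase (2688 against 1.8, at least 71.3-fold), the growth factor MDK (57.4-fold) and the carbonic anhydrase CA2 (53.3-fold).

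The lowest genes with several agreeing probe sets were PEG10, LRATD1, GNAI1, FAR2, NIBAN1, MSMB, UBE2QL1 and PCDH10. PEG10 had signals of 288 in ALDH-positive and 23466 in ALDH-negative cells and a median over its probe sets of -5.57 (SD over 2 probe sets 1.10). LRATD1 was at least 101-fold lower and the inhibitory G protein subunit GNAI1 at least 26.7-fold lower. The fatty acyl-CoA reductase FAR2 was 25.7-fold lower, MSMB 21.9-fold lower and NIBAN1 19.7-fold lower. The protocadherin PCDH10 was 14.6-fold lower and UBE2QL1 12.6-fold lower. Among genes with 1 bright probe set the lowest were CSTA (90.2 against 24240), MALRD1 (at least 132-fold), the growth hormone receptor GHR (at least 91.2-fold) and the cytokine IL20 (at least 42.9-fold).

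Of 33 lists with at least 5 kept genes, 9 lay outside the percentile limits, 8 of them higher and 1 lower. Lists of randomly drawn genes would give 1.65. Members of a real list can vary together, which widens the spread of its median, so 9 against 1.65 does not measure an excess over chance. The 9 lists held 140 kept genes, and 0 of these were in more than 1 of the 9. The pluripotency and self-renewal list had 16 kept genes with a median of 1.03, where random lists reached 0.33 at the upper limit. The list held 8 genes at least 2-fold higher and 0 at least 2-fold lower. SOX2 read 3379 against 104 and ID1 12845 against 941, while ID4 was at least 19.4-fold and KLF5 6.39-fold higher. MYC (0.11), EZH2 (0.28) and KLF4 (0.31) of the same list were under 2-fold. The basal and myoepithelial list had 9 kept genes of 16 measured, with a median of 1.60 at percentile 99.99. Of the 9, 5 were at least 2-fold higher and 0 at least 2-fold lower, while CDH3 (-0.76) and ITGB4 (-0.46) were lower by less. CAV1 led the list, followed by the laminin chain LAMB3 (6.02-fold), the smooth muscle actin ACTA2 (4.57-fold) and CAV2 (4.26-fold), whose other kept probe set differed by 0.93. EGFR, with a difference of 0.88, had 30 neighbouring genes whose median was 0.63.

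The mesenchymal list had 7 kept genes of 22 measured, with a median of 1.42 at percentile 99.9, and its members opposed each other. The transcription factor SNAI2 was at least 8.80-fold higher, TGFBI 5.39-fold and fibronectin, FN1, 5.07-fold higher, whereas TWIST1 was at least 8.64-fold lower. Its place rested on the filter, since without it the list stood at percentile 51.0 and with the filter at the 50th percentile at 96.1. The retinoic acid list had 10 kept genes with a median of 0.95 at percentile 99.9, with 4 at least 2-fold higher and 0 at least 2-fold lower. TGM2 was at least 7.32-fold higher, the retinal reductase DHRS3 4.18-fold, the retinoid X receptor RXRA 2.31-fold and the retinoic acid receptor RARG 2.05-fold higher. RXRA's other kept probe set differed by -0.03, and RARG kept 2-fold in 5 of the 10 settings that held it, with a lowest difference of 0.87. With the filter at the 75th percentile the list stood at 87.4.

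The xenobiotic and oxidative stress list had 26 kept genes with a median of 0.43, where random lists reached 0.23 at the upper limit. The list held 6 genes at least 2-fold higher and 0 at least 2-fold lower. Its largest differences were those of the aldo-keto reductases AKR1C3, AKR1C2 (8.60-fold), AKR1C1 (7.91-fold) and AKR1B10 (3.97-fold), close relatives whose probe sets except that of AKR1C3 carry the shared-transcript suffixes. CYP1B1 (2.93-fold) and CYP1A1 (2.83-fold) were also at least 2-fold higher. Without probe sets of the shared-transcript kind the list's median was -0.10, at percentile 19.9. That setting also left out the brightest probe sets of CYP1B1, NQO1 and FTL, so these values do not measure the AKR1 genes alone. With the filter at the 75th percentile the list stood at 97.4. The interferon list had 17 kept genes with a median of 0.49, at percentile 99.2, with 5 at least 2-fold higher and 1 at least 2-fold lower. HLA-C was 10.8-fold, IFITM1 7.37-fold, HLA-B 4.56-fold and the immunoproteasome subunit PSMB9 at least 6.06-fold higher, while ISG15 and B2M differed by 0.04 and 0.10. Without the shared-transcript probe sets, which include those of HLA-B and HLA-C, this list stood at 95.5.

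The NF-kappaB list had 9 kept genes with a median of 0.73, at percentile 98.2, with 3 at least 2-fold higher and 0 at least 2-fold lower. TNFAIP2 was 10.6-fold, the chemokine CXCL8 at least 9.40-fold and RELB 2.53-fold higher, and the inhibitor NFKBIA had a difference of 0.85. Once the median of neighbouring genes was subtracted, a step chosen after seeing the data, the list stood at 94.7. The unfolded protein response list had 24 kept genes with a median of 0.24, at percentile 97.7, with 0 at least 2-fold higher and 1 at least 2-fold lower. DNAJC3 (1.998-fold) and the chaperone HSPA5 (0.74) were at its upper end, ATF4 (-0.82) and CRELD2 (-1.59) at its lower end, and this list came inside the limits under 4 of 11 alternatives, with percentiles from 53.5 to 98.6. CRELD2 and ATF4 had neighbouring genes with medians of -0.78 and -0.66.

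The hypoxia list was lower, with 22 kept genes, a median of -0.53 and a percentile of 0.01. Of its members 6 were at least 2-fold lower and 2 at least 2-fold higher. STC1 was 8.03-fold lower by a probe set with signals of 775 and 6226, BHLHE40 5.29-fold lower and the glycolytic regulator PFKFB4 2.89-fold lower, while the prolyl hydroxylase EGLN3 was 3.16-fold higher. VEGFA had a difference of -1.25 by its brightest probe set and a mean of -0.88 over its 4 kept probe sets. The pluripotency, basal and hypoxia lists stayed outside the limits under all 11 alternatives, of which median centring and both floors left the percentiles as they were.

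**Figure D2:**
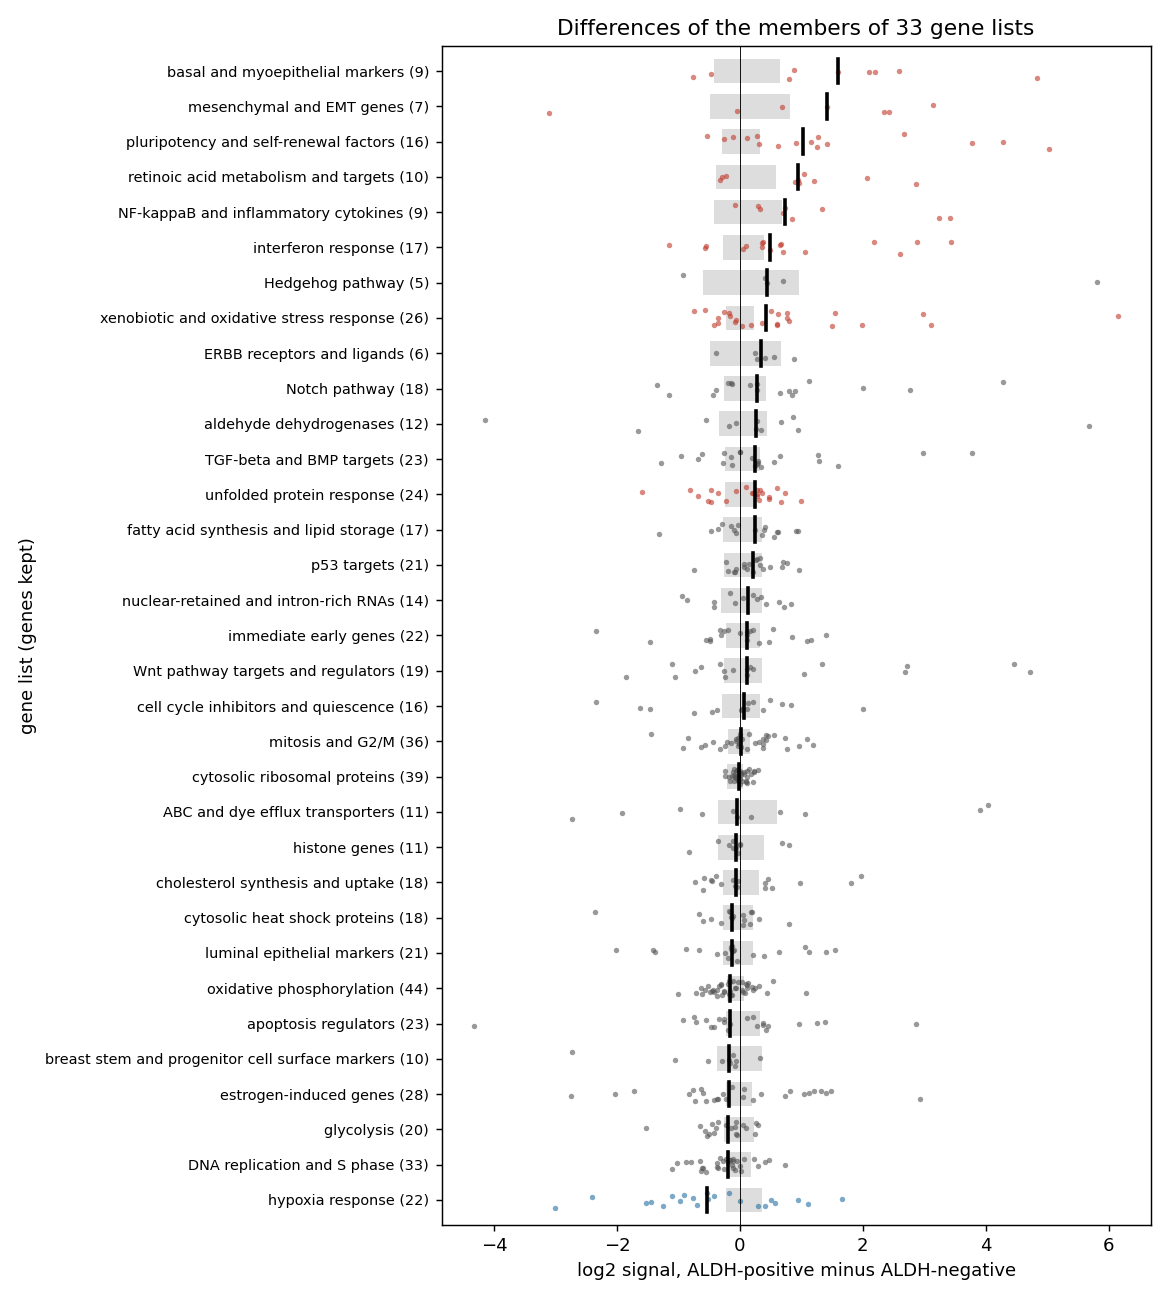
Differences of the kept members of the 33 gene lists, as log2 signal in ALDH-positive minus ALDH-negative cells (x axis), with the number of kept genes beside each list's name. Points are genes, black bars are list medians, grey bars span the percentile limits of random lists matched on signal, and the coloured points belong to the 8 lists above (red) and the 1 list below (blue) that span.

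Luminal keratins and the estrogen receptor were bright on both arrays. The keratins KRT8 (48321 against 57283) and KRT18 (59516 against 67794) differed by -0.25 and -0.19, and ESR1 (12530 against 8032) by 0.64. Of 21 luminal markers, 4 were at least 2-fold higher, among them AGR2 (2.93-fold), and 3 at least 2-fold lower, among them TFF3 (4.06-fold); the list's median of -0.14 lay at percentile 16.7. Of 28 estrogen-induced genes (median -0.18, percentile 5.68), 7 were at least 2-fold higher, with PDZK1 at 7.65-fold. At least 2-fold lower were 3, with the receptor kinase RET at 6.73-fold. The surface markers used to define breast stem cells did not stand apart, with a median of -0.17 at percentile 17.6. CD44 was 2.09-fold lower by its brightest probe set and its 9 probe sets had a median of -0.58, CD24 differed by -0.07, and CXCR4 was 6.62-fold lower.

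The lists of developmental pathways lay inside the limits and had members that differed strongly, several of them in opposite directions. In the Notch list (18 genes, percentile 88.1) 4 genes were at least 2-fold higher, with HEY2 and MAML2 (at least 6.81-fold) in the lead. At least 2-fold lower were 2, the Notch targets HEY1 (2.54-fold) and HES1 (2.23-fold, 2801 against 6255). HES1's other kept probe set differed by -0.34. The Notch list came outside on the high side when the probe sets of a gene were averaged (97.9) and without the shared-transcript probe sets (99.8). In the Wnt list (19 genes, percentile 66.3) 6 genes were at least 2-fold higher and 3 at least 2-fold lower. The secreted inhibitor DKK1 was 26.5-fold higher, at 20023 against 756, CCN5 21.99-fold, AXIN2 at least 6.55-fold and FZD2 6.40-fold higher, while RNF43 was 3.63-fold lower. With the median of neighbouring genes subtracted the Wnt list stood at 98.2. The Hedgehog list (5 genes, percentile 81.6) held SHH and CDON, the latter at -0.93. In the TGF-beta and BMP list (23 genes, percentile 92.7) 5 genes were at least 2-fold higher, led by ID1 and TGFB2 (7.87-fold). In the same list 1 was at least 2-fold lower, the inhibitory SMAD7 (2.44-fold). Among ERBB receptors and ligands (6 genes, percentile 83.4) EGFR by its brightest probe set and ERRFI1 (0.55) differed by under 2-fold, while EGFR's other kept probe set differed by 2.46; without the filter this list stood at 97.6, just outside. Among ABC transporters (11 genes, percentile 25.4) 3 were at least 2-fold higher, with the cholesterol exporter ABCA1 at least 16.5-fold and ABCC3 at least 14.9-fold. Those at least 2-fold lower were 2, ABCA12 (6.64-fold) and the dye efflux pump ABCG2 (3.76-fold, 375 against 1412).

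Growth and metabolic lists lay inside the limits, some of them close to the lower one. The proliferation marker MKI67 read 2119 against 2202. The DNA replication list (33 genes) had a median of -0.19 at percentile 3.70, with TYMS 2.15-fold and MCM5 2.02-fold lower and 26 of the 33 genes below 0. It came outside on the low side after quantile normalization (2.09), after loess (2.33) and with the median of neighbouring genes subtracted (0.89). The mitosis list (36 genes, percentile 61.7) held CDK1 at 2.74-fold lower by its brightest probe set, with a median of -0.93 over its 4 probe sets, and ASPM at 2.29-fold higher. Cell cycle inhibitors (16 genes, percentile 64.3) included KLF2, 5.05-fold lower, and CDKN2B, 4.03-fold higher among neighbouring genes with a median of 0.71. Histone genes (11 genes, percentile 35.5) ranged from H2BC9 at -0.82 to H3-3A at 0.79. The glycolysis list (20 genes, percentile 7.94) held PFKFB4 and PFKP (-0.64), and came outside on the low side without the shared-transcript probe sets (1.26) and with neighbouring genes subtracted (1.57). Oxidative phosphorylation (44 genes, percentile 7.45) held NDUFA5 at 2.11-fold higher and NDUFV2 at 2.01-fold lower. Ribosomal protein genes (39 genes, percentile 85.2) ranged by their brightest probe sets from RPL34 at -0.25 to RPL27 at 0.29. Other kept probe sets of these genes differed by more, among them those of RPS28 (-1.35), RPS6 (-1.33) and RPL18 (1.13).

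In cholesterol synthesis (18 genes, percentile 28.8) STARD4 was 3.93-fold and TM7SF2 3.49-fold higher, and in fatty acid synthesis (17 genes, percentile 89.4) ELOVL5 was 2.49-fold lower while GPAM differed by 0.94; this list stood at 98.6 without the shared-transcript probe sets and at 34.5 with probe sets averaged. Among cytosolic heat shock genes (18 genes, percentile 21.1) HSPB8 was 5.15-fold lower and DNAJA1 differed by 0.80. The immediate early list (22 genes, percentile 68.5) held KLF2 and KLF6 (2.75-fold lower), and the p53 list (21 genes, percentile 84.3) held FAS (0.96) and SPATA18 (0.76). Among apoptosis regulators (23 genes, percentile 6.82) BCL2 was lower and the initiator caspase CASP8 7.30-fold higher.

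Markers of other cells were nearly without signal. Of 37 measured markers of leukocytes, fibroblasts and endothelial cells, 5 were kept and 0 differed by 2-fold, so neither list could be placed in the main setting. Without a filter the leukocyte list stood at percentile 51.2 and the fibroblast and endothelial list at 50.4. With the filter at the 50th percentile they stood at 47.0 and 65.25. The 2 kept leukocyte markers were CD79A (0.07) and CORO1A (0.76), and the 3 others were COL1A1 (-0.04), which is also in the mesenchymal list, PECAM1 (0.80) and EMCN (0.59). A list of nuclear-retained and intron-rich RNAs, used as a sign of RNA quality, had 14 kept genes and a percentile of 76.5, with PNN at -0.94 by its brightest probe set but a median of 0.43 over its 5 probe sets, and KCNQ1OT1 at -0.86.

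Genes that neighbour each other in the genome differed in the same direction on these arrays. The correlation of differences between adjacent kept genes was 0.24 across genes with differences limited to 1 in size on log2, and 0.18 without that limit, and 11 stretches of at least 20 genes had running medians past 0.5 in size, 5 lower and 6 higher. In the stretch from KDELR3 to MAPK8IP2 the 100 kept genes had a median of -0.74 and 86.0% of them were lower in ALDH-positive cells. The 58 genes from DOCK8 to NFX1 had a median of 0.84 and the 66 genes from GGCT to CHCHD2 a median of 0.80.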

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

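The tests of gene density, probe-set noise, other cells and another cell line, the count of stretches, and the subtraction of neighbouring genes as a setting, were chosen only after the results were seen. The other tests had bounds written before their own values were computed, but after the neighbouring genes and the list results had been explored.

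Data outside the gene analysis drew attention because they held differences of the same order. Of 2850 probe sets that passed the filter without a single gene name, 247 were at least 2-fold higher in ALDH-positive cells (8.67%) and 157 at least 2-fold lower (5.51%), with no control samples to set them against.

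Genes that neighbour each other differed together over long distances. The 5 most gene-dense chromosomes spanned 0.61 in their median differences, from -0.46 to 0.16, which argues against base composition, as far as gene density stands in for it, as the whole cause. With differences limited to 1 in size on log2, the correlation between genes 10 to 30 places apart was 0.0987 (0.0546 without that limit), above the highest of 100 shuffled gene orders (0.0073) but under the bound of 0.1 set beforehand for a regional difference such as copy number, which therefore stays undecided, although shuffled orders gave at most 1 stretch where the data gave 11. That correlation was 0.408 of the one between adjacent genes, so overlapping transcripts or clusters of similar genes may add to it. The sorted state itself was not tested, and no DNA measurement was analysed here.

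Many genes differed by 8-fold or more in both directions although the sort was from 1 line. Noise of single probe sets is argued against only for the 66 genes of this kind with several kept probe sets. Of these, 66 (100%) differed by 2-fold or more the same way in every kept probe set. The filter favours this outcome, since a further probe set that is dim on one array is kept only if it is bright on the other. With dim probe sets included, 54 of 109 genes differed so in every probe set, and for the remaining genes noise is not decided. RNA from leukocytes, fibroblasts or endothelial cells is argued against by 0 of the 37 measured markers differing by 2-fold among the 5 that passed the filter, with median marker signals of 16.1 and 18.6. Another cell line on one array cannot be told apart from the sorted state, since 35.4% of 48 luminal and estrogen-induced genes differed by 2-fold, above the 15.4% of all kept genes but not a majority, and no reference profile of MCF-7 was used here. Sublines or clones within the line were not tested and stay open with the sorted state.

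The gene lists that stood apart were weighed against the regional pattern and shared probes. After the median of neighbouring genes was subtracted, 7 of the 9 lists stayed outside the limits, and the unfolded protein response and NF-kappaB lists came inside. The median of neighbouring genes thus did not account for the place of the 7. The step cannot decide on the regional pattern as the cause, since a median leaves in differences that only a few neighbours share. For the basal (median 1.60), mesenchymal (1.42) and pluripotency (1.03) lists the outcome was also nearly fixed, since medians of neighbouring genes varied little (SD 0.27). The same step brought 5 others outside, for 12 in all: DNA replication (0.89), glycolysis (1.57) and estrogen-induced genes (2.17) on the low side, ribosomal proteins (97.7) and Wnt (98.2) on the high side. For the xenobiotic list, signal shared between AKR1 paralogs may account for its place: without its AKR1 genes the percentile was 86.3 and the median of the other 22 genes 0.11. A true difference of the AKR1 genes would give the same value, and AKR1C3, whose probe set is not of the shared kind, differed most.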

How the results depend on the processing

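The subtraction of neighbouring genes was the only alternative chosen after seeing the data. The counts of 983 genes higher and 660 lower stayed within 1.5 times under 6 of the 8 settings chosen beforehand that could move them, and under the added one (818 and 656). Without a filter 1551 genes were higher, and at the 75th percentile 468 were higher and 427 lower and 4 lists lay outside the limits; these settings test more and fewer genes. Over all named probe sets the arrays correlated with r = 0.957, against 0.8995 over those kept and 0.889 over all probe sets with signals raised only to 1; the floor gives dim probe sets 1 constant per array, so 0.957 does not show that they agree better. The xenobiotic list reversed to -0.0962 without shared-transcript probe sets, on which its AKR1C1, AKR1C2, AKR1B10, CYP1B1, NQO1 and FTL values lie, among others. In that setting 7 lists lay outside, 4 of them among the 9. The mesenchymal, NF-kappaB and Hedgehog lists had fewer than 5 genes there and at the 75th percentile and gave no value. Of 84 named genes at 2-fold or more, 72 stayed there in every setting that kept them, and 0 changed sign; RXRA, RARG, CD44, CAV2, TYMS, MCM5, CDK1, ASPM, NDUFA5, NDUFV2, CRELD2 and KLF6 did not stay. Higher genes made up 59.8% of those at 2-fold, and 52.5% after quantile normalization. The floor tests nothing about these counts, since a kept gene with 1 side at the floor is past 2-fold at any floor tried. The absence of replicates and of detection calls limits what dim genes can show. No paired analysis was possible because each group has 1 array and the replicate number only names it.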

Other observations

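The gene families described here were picked only after their values were seen. All 7 kept metallothioneins, zinc- and copper-binding proteins induced by metals, were at least 2-fold lower in ALDH-positive cells, with a median of -2.72. MT2A read 4225 against 27867 and MT1X 3081 against 18878, while MT1E had the smallest difference at -1.82. MT1E's other kept probe set differed by -0.66. The probe sets behind these values carry the suffix of sequences shared within the family, so the 7 are not separate measurements. Of 10 HLA genes and pseudogenes, 7 were at least 2-fold higher with a median of 1.40; HLA-E differed by 0.67 and HLA-F-AS1 by -0.56, and this family too shares probe sequences.

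SGCE, which neighbours PEG10 and is imprinted with it, was 11.1-fold lower, at 374 against 4136, although the 30 genes around the pair had a median of 0.30. Of 9 BEX and ARMCX genes, which lie close together on the X chromosome, 4 were at least 2-fold higher. ARMCX4 was at least 19.1-fold, ARMCX2 at least 17.0-fold and BEX2 14.4-fold higher, while ARMCX3 differed by 0.30 and the genes around them had medians from 0.53 to 0.59. AKR1E2, outside the fixed lists, was 2.10-fold higher beside its AKR1 relatives.

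Some of the strongest differences left little signal on one array. CYBA in ALDH-negative cells was 0.666% of its signal in ALDH-positive cells, and CSTA in ALDH-positive cells was 0.372% of its signal in ALDH-negative cells. The chromosome that carries RPL3 had the lowest median of all, -0.46 over 242 genes, with 76.4% of them lower in ALDH-positive cells.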
